A study of Coffea arabica with 8 samples.

How the data were processed

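Total RNA of Tall Mokka and Typica shoot tips was extracted with a plant RNA column kit and turned into cDNA with indirect Alexa Fluor 555 or 647 labelling, per the labels' protocols. The trees were clonally propagated and field-grown at 1 station, per the labels. The deposited values are log2 ratios between the channels of each array, 1 value per probe, for 15264 probes and 8 arrays. Scanner, background correction, normalization, spot filter and the treatment of repeated spots are not given in the sources used here, and cells that read null were taken as missing (765 to 2267 per array). The log2 scale and the direction were read from the values. On the 4 arrays with Typica in Alexa Fluor 555, 2 to the power of the value was a whole number of steps of 0.001, within 0.02 of a step, for 100% of the values under 2-fold. For the inverse this share was 4.68% to 5.29%. On the 4 arrays with Tall Mokka in Alexa Fluor 555 it was the inverse that gave 100%, and the value itself gave 4.71% to 4.93%. The sign of these arrays was therefore turned after a ratio had been rounded to 3 decimals, and the deposited columns were used without a further change of sign. A second check was fixed before the data were examined: the difference between the arrays numbered 1 and 3 (MA against MB, both with KB) correlated across probes at r = 0.06 and rho = 0.11 between the dye arrangements, which is positive but small. The other planned correlation, of dye-swapped arrays of the same number, lay between -0.28 and 0.03. Differences between other numbers of unlike pool pairs correlated at r from -0.05 to 0.18. These correlations were too small and mixed to decide the relative direction. The scale thus rests on the rounding of the stored ratios. The relative direction rests on it too, if the rounded ratio had the same channel order on all arrays, which is assumed here. Otherwise the 2 dye arrangements would run in opposite directions. The absolute direction rests on a likely reading, and the centring step remains unknown.

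Samples were assigned to pool pairs from their descriptions, and the numbers 1 to 4 in the titles were taken as labels of dye-swapped pairs. Arrays of 1 pool pair were averaged with equal weight for each dye arrangement, which cancels only a dye effect of equal size in both arrangements. The 3 pair means were then fitted by generalised least squares with the pool as the unit of replication. The cultivar estimate is the mean of MA × KA and MB × KB, and the 2 remaining contrasts of the 4 pools give 2 residual degrees of freedom. Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation (prior degrees of freedom 2.13) and Benjamini-Hochberg adjustment at 0.05. No added normalization was applied. Probes needed a value in both dye arrangements of each pool pair (12093 probes). The dye effect was tested with limma on the difference within each dye-swapped pair, divided by 2, over 10312 probes. That p measures only the spread between hybridisations. Spreads and correlations were computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and the error per array was put on the scale of the pool distances by assuming equal error on all arrays. The 95% intervals came from 500 resamples of probes, which treat probes as independent.

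The fits were tested on simulated data: each measured value was given a random sign, and 200 of 12093 probes were shifted by 1, 2 or 4 on the log2 scale. The test on pools recovered 0%, 0% and 70% of them, with 0 false calls in each case. The fit on 8 arrays recovered 48.5%, 81% and 99%, with 2, 4 and 4 false calls. Random signs remove any spread shared by arrays of 1 pool pair or dye arrangement, so the simulation does not test the false calls of a fit that treats arrays as independent.

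The test, the alternatives and 20 gene lists were chosen before the data were examined. The rule for named genes asked for probes past the threshold and, with fewer than 10, for those of smallest p in each direction. For probes without gene names it took 2 per direction. With 0 probes past the threshold these parts of the rule were combined: the 2 probes of smallest p in each direction with the same sign in all 3 pairs are given, and none passed. None of the 15264 identifiers matched the 80883 genes of the coffee gene table (assembly ET-39 HiFi), so the gene lists were not used. The alternatives tried covered other fits of the spread, moderation, centring, scaling, quantile normalization, single dye arrangements, handling of the repeats, the pool labels of the arrays numbered 4, filters, thresholds and leaving out each array and each number. Removal of prefix and number medians (3 sweeps), turning back the signs of 4 arrays, weights for pairs or arrays and spreads without the widest array were chosen after seeing the data.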

Results

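Shoot tips of 2 coffee (Coffea arabica) cultivars, Tall Mokka and Typica, were compared on 8 two-colour arrays. The tips, taken with the still closed first leaf pair, came from 6 Tall Mokka and 8 Typica trees. Trees of each cultivar were divided into pools A and B, so that the Tall Mokka pools MA and MB held 3 trees each and the Typica pools KA and KB held 4 each. Every array carried 1 Tall Mokka pool and 1 Typica pool, one labelled with Alexa Fluor 555 and the other with Alexa Fluor 647, and the value of a probe is the log2 ratio between them. According to the sample descriptions, MA was hybridised with KA on 4 arrays, MA with KB on 2 and MB with KB on 2, and in each of these 3 pool pairs the dyes were exchanged on an equal number of arrays. The design text lists a pairing of MB with KA that no sample description carries, and the descriptions were followed. The pool was the unit of replication, with 2 pools per cultivar, and dye swaps and repeats of the same pair were technical.

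The table held 15264 probes, of which 10312 had a value on all 8 arrays. The arrays measured between 12997 and 14499 probes, and their median log2 ratios lay between -0.07 and 0.02. The SD of the log2 ratios was 0.68 to 0.98 on 7 arrays and 1.83 on the MB × KB array with Tall Mokka in Alexa Fluor 555. On that array 34.1% of the measured probes differed at least 2-fold between the channels, against 9.03% to 16.9% on the other arrays. The table holds no spot intensities, and the number of arrays and of pools limits the precision. The rounding of the stored ratios puts all arrays in one direction if the rounded ratios had the same channel order on every array. The sources used here do not state that order. This direction is likely Tall Mokka over Typica, on the basis of the order in which the series names its cultivars and the usual ratio of the longer over the shorter wavelength dye, and "higher" below means higher in Tall Mokka in that reading. Probe identifiers are not paired with gene names in the table, and 0 of them were found in the coffee gene table used here, so probes are given by identifier alone. The sources used here do not name the array or the species of its probes. Whether the probes are coffee sequences is therefore unknown.

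Between Tall Mokka and Typica, no probe passed the test. Of 12093 probes measured in both dye arrangements of all 3 pool pairs, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.991. At an unadjusted p under 0.05 there were 65 probes, 41 higher and 24 lower, while 100 simulated sets with random signs and no shared signal, added after seeing the data, gave 30 to 59. That count was 56 after the medians of identifier prefixes and numbers were removed. Random signs also remove structure shared by arrays of 1 dye arrangement or spot layout, so no excess over chance was shown. Evenly distributed p-values would give 605 probes, far more than the 65, so the test was conservative. The MA × KB arrays enter its residual but not its estimate. The count was 43 without the MB × KB array with Typica in Alexa Fluor 555 and 490 without both arrays of MA × KB, with 0 calls after adjustment in each case. The mean log2 ratio of the cultivars reached 2-fold for 861 probes, 178 higher and 683 lower. Taken singly, MA × KA had 138 probes at least 2-fold higher and 133 lower, MA × KB 315 and 227, and MB × KB 740 and 1233. On the MB × KB array of widest spread, 291 probes were at least 8-fold higher and 1042 lower. The median standard error was 0.32 on the log2 scale. In arrays simulated with the measured spread, the test recovered 0 of 200 probes shifted by 1 on the log2 scale, 0 of 200 shifted by 2 and 140 of 200 shifted by 4, so differences of 4-fold were not detectable with this test. When the 8 arrays were treated as independent replicates with a dye term, so that spread between pool pairs and technical spread were mixed, limma called 5 probes, 4 higher and 1 lower. It called 0 with the number as a replicate block (smallest adjusted p 0.0867) and 0 with the pool pair as a random block (0.140). In the simulation, in which arrays share no spread, that fit recovered 97 of 200 probes shifted by 1 on the log2 scale. A plain rule of at least 2-fold in the same direction in all 3 pairs, without a test, gave 6 probes, all higher.

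The probes with the smallest p in each direction and the same sign in all 3 pairs did not pass either. STMEF64 had a log2 ratio of 1.39 ± 0.26 (SE), a 2.61-fold higher value in Tall Mokka, with an adjusted p of 0.991 in limma, and was higher on 7 of the 7 arrays that measured it. Its values ran from 0.38 to 2.40 over the arrays. STMIT78 had a log2 ratio of 1.20 ± 0.25 (SE), or 2.29-fold, and was higher on 8 of 8 arrays with the narrowest range of the 4 probes, 0.89 to 1.73 (SD 0.27). Its pair means were 1.03 for MA × KA, 1.32 for MA × KB and 1.36 for MB × KB. STMIT78 was 1 of the 5 probes called when arrays were treated as replicates, at an adjusted p of 0.0475 in limma, which became 0.0867 with the replicate block, 0.140 with the pool-pair block and 0.0892 with pools as fixed effects. With pools as fixed effects p measures only the spread between hybridisations, and not that between pools. Both STMEF64 and STMIT78 were among the 6 probes of the plain 2-fold rule. Among probes lower in Tall Mokka, STMGZ39 had a log2 ratio of -1.07 ± 0.25 (SE) and was lower on 6 of 7 arrays, with values from -2.17 to 0.66. Its estimate was -0.11 from the arrays with Typica in Alexa Fluor 555 and -2.04 from those with Tall Mokka in it. The values ran from -0.62 to 0.66 on the former and from -2.17 to -1.36 on the latter. Its size thus depended on the dye arrangement. The estimate was -0.61 without the MB × KB array of widest spread, which leaves that pair with Typica in Alexa Fluor 555 only. STMHX01 had a log2 ratio of -0.996 ± 0.24 (SE) and was lower on 8 of 8 arrays, with values from -2.33 to -0.21. The estimate of STMHX01 was -0.53 without the widest array and -1.46 without the other array of MB × KB, so its size rested in part on single arrays. The adjusted p was 0.991 in limma for each of these probes.

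**Figure D1:**
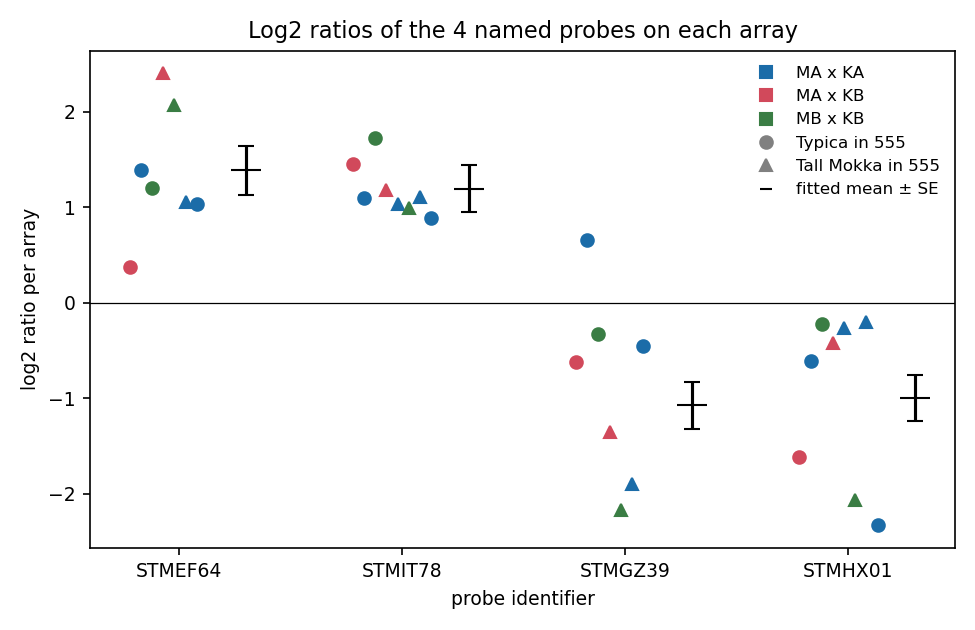
Log2 ratio per array (vertical axis, likely Tall Mokka over Typica) for the 4 probes of smallest p, with colours for pool pairs, circles for arrays with Typica in Alexa Fluor 555, triangles for arrays with Tall Mokka in it, and black bars for the fitted mean ± SE. The 8 values of STMIT78 lie between 0.89 and 1.73, and those of STMGZ39 fall on both sides of 0.

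The design also gives the distance between pools of one cultivar. The difference between the Typica pools KA and KB, each measured against MA, had an SD of 0.58 over the 12093 probes, and 1025 probes (8.48%) differed at least 2-fold. For the Tall Mokka pools MA and MB, each measured against KB, the SD was 1.02 and 2509 probes (20.7%) differed at least 2-fold. Without the MB × KB array of widest spread the SD for MA and MB was 0.89. MB × KB then holds 1 dye arrangement, in which a dye effect does not cancel. These differences include the measuring error of the arrays and have 1 pool on each side, so no test was made. The cultivar mean of MA × KA and MB × KB had an SD of 0.52, and their difference scaled in the same way, in which a difference common to the cultivars cancels, had an SD of 0.47. After the medians of identifier prefixes and numbers were removed, these SDs were 0.49 and 0.46. The gap between them was thus not shown to be a cultivar difference.

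**Figure D2:**
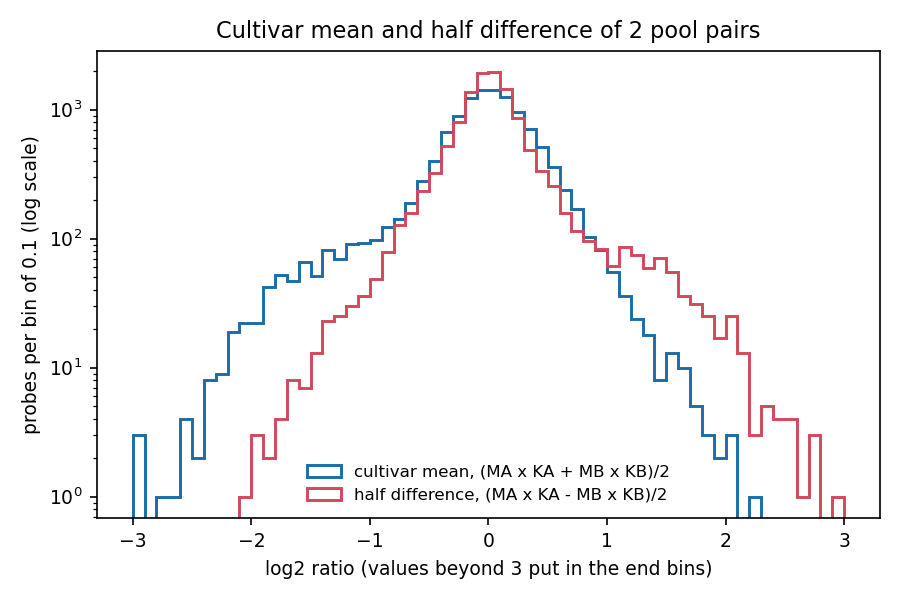
Number of probes (vertical axis, log scale) by log2 ratio (horizontal axis, bins of 0.1) for the mean of MA × KA and MB × KB, which would hold any cultivar difference, and for their difference divided by 2, from which it would cancel. The SDs were 0.52 and 0.47, and 0.49 and 0.46 after medians of prefixes and numbers were removed (not shown).

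The same test was applied to the other ways of dividing the 4 pools into pairs. Setting MA and KA against MB and KB, limma called 0 probes, with 1742 at an unadjusted p under 0.05. For MA and KB against MB and KA it called 0, with 90 at an unadjusted p under 0.05. The cultivar division gave 65. These counts are not comparable with one another, because the simulated sets with random signs gave 30 to 59 for the cultivar division, 1295 to 1437 for MA and KA against MB and KB and 157 to 211 for the remaining one.

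Measuring error was first estimated per array. Arrays described as repeats of MA × KA in the same dye arrangement differed with an SD per array of 0.64 (mean of 2 pairs of arrays, range 0.641 to 0.647). Each of these pairs includes an array numbered 4, for which the design text leaves room for a pairing of MB with KA. With these arrays taken as MB × KA, the cultivar test called 0 probes, with 204 at an unadjusted p under 0.05 in limma. Dye-swapped arrays of the same pools had an SD per array of 0.92 (mean of 4 pairs, range 0.63 to 1.37), and 0.76 without the array of widest spread. The lowest of these pairs, MA × KA number 4, lay below both repeat pairs. The pool distances above are differences between means of arrays. If every array had the error of the repeats, measuring error alone would give an SD of 0.56 between KA and KB and 0.64 between MA and MB, where 0.58 and 1.02 were found. With the error of the dye-swapped arrays it would give 0.79 and 0.92. That error also holds any gene-specific dye effect, which cancels in the pair means where it is equal in both arrangements. These 2 values may therefore be too high. The dye-swapped arrays of MB × KB themselves had an SD per array of 1.37 and those of MA × KB 0.70, so equal error is doubtful. With median centring and MAD scaling the repeat SD was 0.76 and the SD between MA and MB 0.71. A distance between MA and MB beyond measuring error was therefore not shown. Across probes, which are not independent replicates, the repeats in one dye arrangement correlated at r = 0.14 and r = 0.38 (rho = 0.24 and 0.33). Dye-swapped arrays of the same number, turned the same way, correlated at r between -0.28 and 0.03 (rho between -0.14 and 0.13). Over all 12 pairs of arrays in the same dye arrangement the mean r was 0.14, and over the 16 pairs in opposite arrangements it was -0.08. A gene-specific dye effect was called for 0 of 10312 probes by limma, with 1044 at an unadjusted p under 0.05 and a smallest adjusted p of 0.289. The 1044 exceed a share of 0.05 of these probes. Median centring with MAD scaling gave 1239 and a smallest adjusted p of 0.0516 in limma, and removal of prefix and number medians gave 823. The 0 calls therefore do not show that dye effects were absent.

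**Figure D3:**
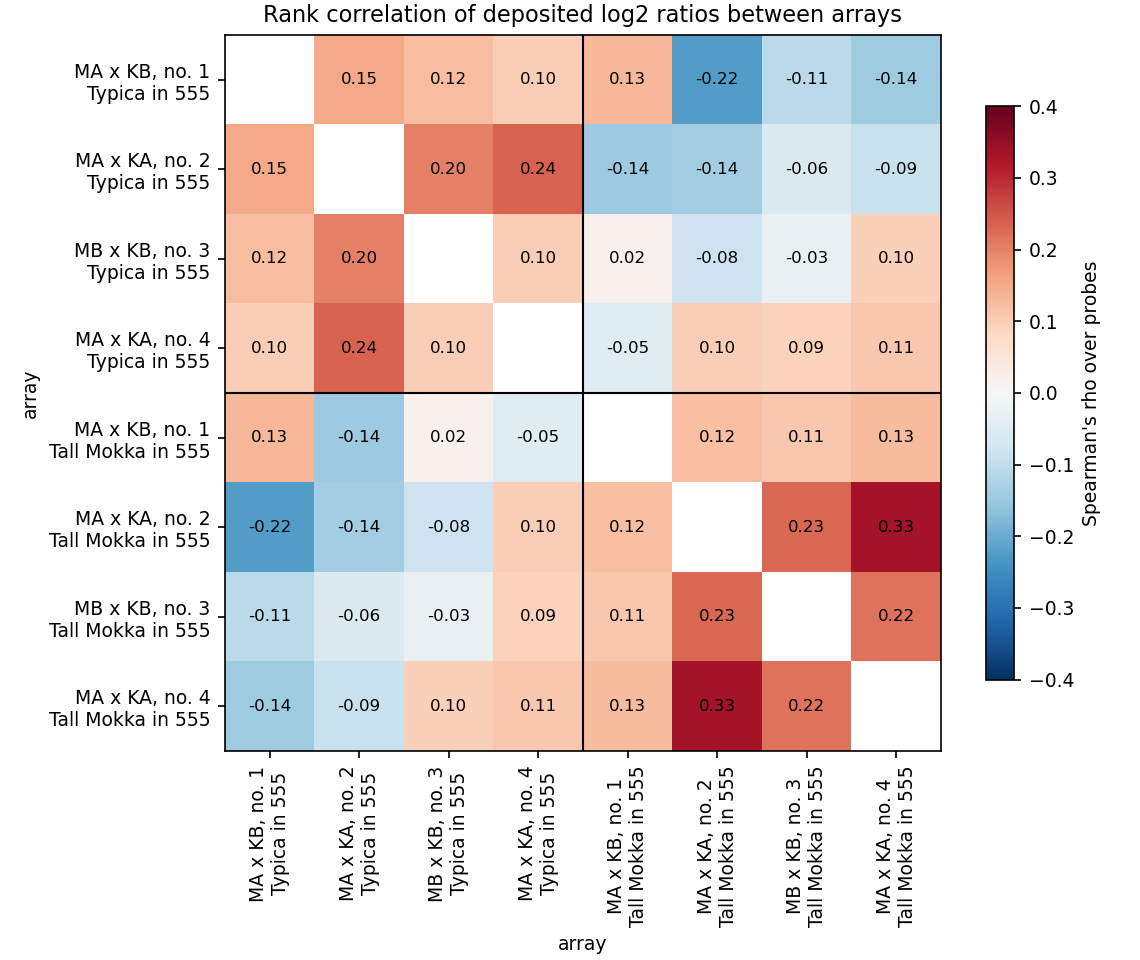
Spearman's rho of the log2 ratios over probes for each pair of the 8 arrays, ordered by dye arrangement, with black lines between arrangements; pool pair and number stand on both axes. All 12 pairs within an arrangement are positive (0.10 to 0.33), and those across arrangements range from -0.22 to 0.13.

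The ratios also varied with the probe identifier, a relation examined only after seeing the data. Identifiers consist of 159 prefixes, each with numbers 1 to 96, and the number accounted for 10.7% of the variance of the cultivar mean over probes, where 200 random reorderings gave at most 1.08%. The profile over the 96 numbers correlated at r = 0.79 between alternate prefixes. In runs of 6 numbers, the mean log2 ratio of MB × KB was -0.48 ± 0.02 (SEM over 2012 probes) at the first number and 0.13 ± 0.02 (1990 probes) at the fifth. For MA × KA it was -0.21 ± 0.01 and 0.12 ± 0.01 at the same numbers, and for MA × KB -0.05 ± 0.01 and -0.05 ± 0.01. After the medians of prefixes and numbers were removed from each array, the cultivar comparison again gave 0 calls in limma, with 56 at an unadjusted p under 0.05, and the fit on arrays gave 0 calls with a smallest adjusted p of 0.0516. In that limma fit STMIT78 had a log2 ratio of 1.11 at an adjusted p of 0.0614, against 1.19 and 0.0475 before the removal. In the test on pools its log2 ratio went from 1.20 to 1.04.

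**Figure D4:**
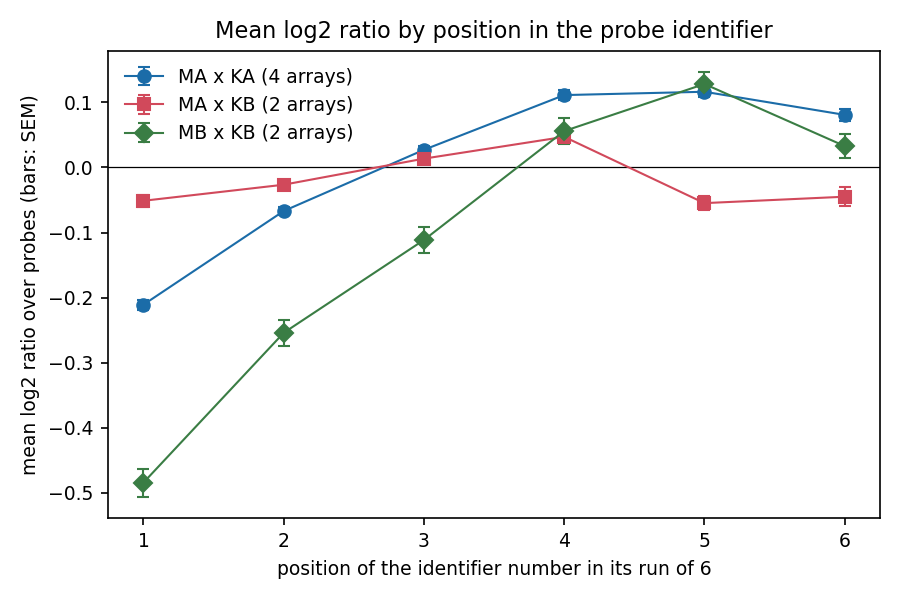
Mean log2 ratio over probes (vertical axis, bars are SEM) by position of the identifier number within its run of 6 (horizontal axis), for the 3 pool pairs. MB × KB and MA × KA lie lowest at position 1, at -0.48 and -0.21, and MA × KB varies least.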

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

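Removed medians, turned signs, weights and spreads without the widest array were added after seeing the data. The count of probes differing between the cultivars was 0 under 35 of 38 alternatives, including all 12 fits that left out an array or a number (range 0 to 0, smallest adjusted p 0.713 to 1.00). Stricter thresholds could only give 0. Dropping the repeats numbered 4, or using them in place of number 2, repeats the fits without number 4 or 2. Most others were forms of the pool test, which recovered 0 of 200 simulated probes shifted by 2 on the log2 scale. The tally is therefore weak evidence of stability. With 8 arrays, a dye term and no block the count was 5. With array weights it was 19, which included the 5. The rule of 2-fold in all 3 pairs gave 6. Both fits on arrays treat arrays of shared pools as independent. The cause was not tested. With the number as a replicate block the count was 0 (correlation within blocks 0.117, smallest adjusted p 0.0867), with the pool pair as a random block 0 (0.140), and with pools as fixed effects 0 (0.0678). The count at an unadjusted p under 0.05 ranged from 8 to 2419 over the alternatives, and was 490 without both arrays of MA × KB. The direction split of called probes and the gene lists have no value to compare. Of 129 alternative values of the 4 named probes, 126 kept their sign, which selecting probes of 1 sign in all 3 pairs favours. The other 3 (STMEF64 -0.18, STMGZ39 0.96, STMHX01 0.15) came from turning back the signs of the arrays with Tall Mokka in Alexa Fluor 555. That reading would be right if the rounded ratios already ran from cultivar to cultivar, which the values do not settle. With it limma called 0 probes, with 199 at an unadjusted p under 0.05 and a smallest adjusted p of 0.828. The main fit gave 65 and 0.991. STMIT78 alone passed the threshold, at a log2 ratio of 1.19 without a block and 1.14 with array weights, with adjusted p from 0.0235 to 1.00 over its alternatives.

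The SD between KA and KB was 0.58, and 0.64 with MAD scaling, 0.62 without the repeats numbered 4, 0.52 with values on all 8 arrays, 0.56 with prefix and number medians removed and 0.60 without the widest array. Between MA and MB it was 1.02, and 0.71, 0.96, 0.95, 0.99 and 0.89 in the same order. The SD of repeats in the same dye arrangement was 0.64, and 0.76, 0.52 and 0.63 with scaling, complete values and medians removed. The cause of these changes was not tested. The repeat SD has no value without the repeats, and the dye effect already required complete values. Dye-swapped arrays had an SD of 0.92, and 0.73 to 1.01 over its alternatives. The dye effect count was 0 under its 4 alternatives. Signal over background, which limits these results, is unknown here.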

Other observations

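The tests of covariance and the counts of sign patterns and missing cells in this part were chosen after the results were seen; the tests of pool splits, dye effect and the arrays numbered 4 were planned.

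Of the 10312 probes with all 8 values, 406 (3.94%) had the same sign on every array, 179 higher and 227 lower (201 and 190 of 391 with each array centred on its median), on arrays that share pools and so are not independent. Among the 128 possible patterns of agreement and opposition between the arrays, this was the most frequent. The next had 280 probes and was the pattern of opposite signs in the 2 dye arrangements, and the arrays of MA × KB opposed to all others came to 271. The median over patterns was 61.5. With prefix and number medians removed, the numbers were 339 for agreement, 248 for MA × KB opposed to the others and 174 for opposite signs in the 2 dye arrangements.

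The missing values also followed the identifier. In runs of 6 identifier numbers, 3.56% of cells were missing at the second number and 16.8% at the last.

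For the number of called probes, the 4 pools allow only 3 divisions into pairs, too few for a share under 0.05. All 3 gave as many calls as the cultivar division, with 0 calls for the cultivars and 0 as the highest of the others. As the number of called probes was 0, a gene-specific dye effect among calls could not be examined.

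The arrays numbered 4 were tested for a wrong label, since the design text names a pairing of MB with KA. If they carried MB, their difference from the arrays numbered 2 should follow the difference between numbers 3 and 1. The correlations across probes were -0.043 and -0.057 in the 2 dye arrangements, under the bound of 0.1 set beforehand for a correct label. That bound was badly chosen, because the same MB against MA difference measured in both arrangements correlated at only 0.064, so the labels MA × KA and MB × KA cannot be told apart here.

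The pool pairs MA × KA and MB × KB share no pool, yet their log2 ratios covaried over probes (covariance 0.0533, and 0.0289 or 0.0992 without the widest or the other array of MB × KB). Removing prefix and number medians left 0.0266 (95% interval 0.019 to 0.0331), and 0.0298 or 0.0462 without the same arrays, which argues against position in this form as the whole cause, and any part of it rests on the widest array. A difference between the cultivars present in all pools, as the sole source, would need MA × KB to covary with both pairs at least as strongly, if pool differences are unrelated to it. After the removal the covariance of MA × KB with MA × KA was -0.00311 (95% interval -0.00666 to 8.46e-05) and stayed under that of MA × KA with MB × KB when any one of the 8 arrays was left out, while that of MA × KB with MB × KB, 0.00184, ranged from -0.024 to 0.0273. A position effect of another form, an error specific to the MA × KB arrays, and a cultivar difference masked by either remain open.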
